A study of Rattus norvegicus with 85 samples.

How the data were processed

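Liver RNA of male Sprague-Dawley rats was compared with a reference on 2-colour cDNA arrays. Per the labels, rats had been assigned at random to oral gavage with clofibrate, gemfibrozil, Wyeth 14,643, phenobarbital or D-mannitol and were killed 24 h after dosing began or after 2 weeks of dosing. The 3 peroxisome proliferators were given in a carboxymethylcellulose and Tween vehicle and phenobarbital in water, so that compound class and vehicle differ together. The vehicle of D-mannitol is not given, and no group was given vehicle alone. D-mannitol was measured at 2 weeks only. Doses, the dyes of the channels and the source of the reference RNA are not given in the sources used here.

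The deposited values are log2 ratios, 1 per probe and array, between a channel the labels call reference and a channel that holds liver RNA. How the authors subtracted background, filtered spots or normalized arrays is not given in the sources used here. The base of the logarithm was read from the values: they run from -10.7 to 14.2, inside the bound of 16 that scanner values of 16 bits set for log2 and outside those for the natural log (11.1) and log10 (4.82). The direction, liver over reference, is likely and not settled; it rests on the order of the channels in the labels and on positive values of Ephx1, a known phenobarbital-inducible gene, on the phenobarbital arrays. If it ran the other way, every sign in the text would turn. Array medians ran from -0.42 to 0.92 (median 0.11) as deposited, so the authors' values were not centred at 0 on each array.

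The table holds 1693 probes. The platform annotation gives 1 gene symbol for 1428 of them, several for 32 and none for 233, and 1421 of the 1428 symbols were brought up to date through their Entrez number (7 were not found there). Probes of 1 gene were averaged, which left 1689 features, 1424 of them named genes. The 4 genes with 2 probes agreed poorly between animals, with correlations of 0.37 for Afp, -0.42 for Crp, -0.21 for Cyp2j3 and -0.24 for Myl12b. Gene names are those of the annotation, and clone sequences were not checked.

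Each array was centred on its median over all probes. The 3 arrays of an animal (4 for 1 clofibrate animal at 2 weeks) were then averaged to 1 value, and a feature was tested where at least 2 animals of each group had one. The number in an array's title that precedes the array number was taken as the animal, which gives 28 animals: 3 in each group and 4 with D-mannitol. The groups share no animal numbers. The numbers are read as animals because the labels speak of 3 rats per group; if they marked something else, p-values would measure a technical spread.

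A share of the values on each array, 0.363% to 43.2% (median 2.13%), stood at a single repeated value, called the floor here, and 0% to 31.5% (median 2.42%) lay beyond 4 on the centred log2 scale. The floor need not be the lowest ratio of an array. On array 72, of clofibrate animal 35 at 24 h, it held 43.2% of probes and equalled the array's median (-0.42). On that array 16 probes lay more than 4 below the median. A value at the floor is therefore not a low ratio as such. Across features, the share of a gene's values at the floor or beyond 4 rose with its mean log2 ratio in every group but clofibrate at 24 h (Spearman -0.048 there, 0.335 to 0.796 elsewhere). Values above 4 are part of this share and raise the mean, so the relation cannot tell whether the floor sets the ratios of any gene. Values without floor and tail are given where a gene had many of them. Of 3570 pairs of arrays, 0 held identical values. Array correlations over all probes had a median of 0.362 within an animal, 0.334 between animals of a group, 0.270 between groups at the same time and 0.174 between times. Array 130, of D-mannitol animal 60, correlated at -0.397 to 0.168 with the other arrays of its group, and it was part of all 18 pairs below -0.3 (lowest -0.447). Its direction is therefore not settled, and results with D-mannitol were also computed with its sign turned and without it.

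Array numbers fell into separate ranges at each time: 50 to 77 (21 arrays) and 82 to 100 (15) at 24 h, and 102 to 135 (21) and 137 to 179 (28) at 2 weeks. The ranges differed in how their values were spread, with medians of 15.2%, 3.78%, 1.54% and 0.768% of probes at the repeated value, and groups were spread unevenly over them. They are called array series here and were treated as batches. Arrays 50 to 77 and 137 to 179 hold every animal, and the other series hold 1 to 3 animals per group: 1 with Wyeth 14,643 at either time and with clofibrate at 2 weeks, and 2 with clofibrate at 24 h. Tests within those series took features with a value in 1 animal per group, and a lone animal was assumed to vary like the other groups. No series holds both times, so time and series cannot be told apart.

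Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in a single fit of the 9 groups. All adjusted p-values of single features are from limma with the Benjamini-Hochberg method over the 1689 features of a comparison, with a threshold of 0.05. Differences are given on the log2 scale as the estimate ± its standard error, with n = 3 animals per treated group (9 for the 3 peroxisome proliferators together) and 4 for D-mannitol. The 3 proliferators together enter as the mean of their groups, and the standard error leaves out the spread between these compounds. There were 26 comparisons: 9 of a group against the reference, 3 of the peroxisome proliferators with phenobarbital (24 h, 2 weeks and the change between them), 6 between single proliferators, 4 against D-mannitol and 4 between times. A comparison with the reference leaves out the spread of the reference, which was not measured.

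The pathway, complex and cell marker lists numbered 28, and 25 of them had at least 5 measured genes and were tested with limma's camera (preset correlation of 0.01 between genes, adjusted over the 25 lists of a comparison). In all, 129 of 650 such tests passed, but only 7 did with a correlation estimated for each list, and that second adjusted p is given with each list call. Counts of list members are over all features, with the count adjusted over the list alone beside them. The resemblance of animals was tested with an exact one-sided permutation test over all 15400 partitions of 12 animals into 4 groups of 3.

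Genes to be named were chosen by a rule: for each comparison the 6 highest and 6 lowest genes past the threshold whose animals did not overlap between the sides (a condition not applied to the change between times, which compares 2 differences), up to 3 members of each list with the largest change, and a set of 28 genes tied to these compounds, of which 11 were measured. A gene outside this rule is said to be so. The groups, tests, lists, the naming rule and a first set of alternatives were chosen before the data were examined. That first set held uncentred values, quantile normalization, all arrays with the animal as a random block (correlation within animals 0.0436), fits on the groups compared alone, each probe on its own, features with a value on every array, leaving out each animal, other measures of resemblance, an estimated correlation and fry for lists, and a threshold of 0.01 for overlaps. Those added after seeing the data were values without floor and tail, each array series alone, the series as a term, and array 130 turned or left out. The fit with the series as a term took all arrays as samples, with the animal as a random block (correlation within animals 0.0852). Its counts therefore differ from the main ones in the unit of replication as well as in the series.

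The fit was tested on simulated data for Wyeth 14,643 minus D-mannitol, with 200 of the 1689 features changed and independent genes, in 50 draws. Of features changed by 1 on the log2 scale 49.6% were found (40 to 62%) and of those changed by 2, 72.2% (63 to 82%). On average 4.08% of the calls were false (0 to 9.63%), and a comparison without any change had at most 1 call.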

Results

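Livers of 28 male rats were measured on 85 arrays, each set against a reference. At 24 h there were 3 animals with each of clofibrate, gemfibrozil, Wyeth 14,643 and phenobarbital, and at 2 weeks there were 3 with each of these and 4 with D-mannitol, a sugar alcohol. The first 3 compounds are peroxisome proliferators, which act on the nuclear receptor PPAR alpha, and phenobarbital is a barbiturate known to induce drug-metabolizing enzymes. Each animal had 3 arrays, apart from 1 clofibrate animal at 2 weeks with 4, and 1689 features were compared. The title of the series asks about chemical-specific profiles, so the first question was whether animals given 1 compound resembled each other more than animals given another.

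On average animals of 1 compound resembled each other more than animals of different compounds at 24 h, and by a smaller margin at 2 weeks, where clofibrate was an exception. At 24 h the correlation over all features averaged 0.490 within compounds and 0.281 between them, a difference of 0.209 (exact one-sided permutation test over 15400 partitions of the 12 animals, p = 6.49e-05, the smallest possible). Gemfibrozil animals correlated at 0.680 with each other, phenobarbital animals at 0.536, Wyeth 14,643 animals at 0.436 and clofibrate animals at 0.309. Gemfibrozil and phenobarbital animals correlated at 0.542 with each other, above the values within phenobarbital, Wyeth 14,643 and clofibrate. At 2 weeks the averages over the same 4 compounds were 0.703 and 0.676, a difference of 0.0270 (exact permutation test, p = 0.0262). D-mannitol animals, which were not part of that test, correlated at 0.675 with each other. They were at 0.681 with gemfibrozil animals and at 0.608 to 0.659 with the other groups. Gemfibrozil, Wyeth 14,643 and phenobarbital animals were at 0.740, 0.739 and 0.731 within their groups. Clofibrate animals were at 0.60, below their values with gemfibrozil (0.678), phenobarbital (0.654), Wyeth 14,643 (0.615) and D-mannitol (0.608). Within the array series that holds every animal the difference was 0.141 at 24 h (exact p = 6.49e-05) and 0.0285 at 2 weeks (exact p = 0.0841). At 2 weeks the difference in that series was about as large as over all arrays, but its p was above 0.05, as it was with the more variable features alone (0.0271, exact p = 0.0710), whereas with quantile normalization the difference was 0.0784 and with Spearman's correlation 0.0864 (exact p = 6.49e-05 for both). Features are not independent replicates, and 2 such relations were tested, 1 per time.

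After 24 h livers of the peroxisome proliferators held more mRNA of most measured genes of mitochondrial fatty acid oxidation than phenobarbital livers, and less of drug-metabolizing enzymes. Vehicles differed with the class of compound, carboxymethylcellulose and Tween for the proliferators and water for phenobarbital. Of 14 measured genes of mitochondrial fatty acid oxidation 11 were higher with the proliferators and none was lower (11 adjusted over the list alone), with a median difference of 0.80. Among them, Eci1, an isomerase of the oxidation of unsaturated fatty acids, was higher by 1.55 ± 0.16 (n = 9 and 3 animals, adjusted p = 8.19e-07) and Acat1, which acts on acetoacetyl-CoA, by 1.43 ± 0.21 (7.31e-05). Acsl1 and Slc27a2, which activate fatty acids, were higher by 1.25 ± 0.16 (1.91e-05) and 0.99 ± 0.17 (3.37e-04). The lists of peroxisomal and microsomal fatty acid oxidation (2 of 14 higher, 2 adjusted over the list alone; median -0.02, camera adjusted p = 0.552) and of fatty acid uptake and lipoproteins (2 of 14 higher, 4; 0.15, 0.310) did not pass. Ephx1, the microsomal epoxide hydrolase, was at -2.10 ± 0.23 relative to phenobarbital (2.24e-06), the glutathione transferase Gsta2 at -2.27 ± 0.34 (7.83e-05). Alas1, the first enzyme of haem synthesis, was at -1.75 ± 0.23 (2.21e-05).

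Among named genes, Grk5 and Ppp5c had the smallest adjusted p at 24 h. Ppp5c, a protein phosphatase, was higher with the proliferators by 4.0 ± 0.27 (adjusted p = 1.07e-09; 3.78 without floor and tail values) and Grk5, a receptor kinase, by 2.31 ± 0.14 (2.42e-10). The water and glycerol channel Aqp3 was higher by 3.35 ± 0.70 (0.00302; 2.84 without floor and tail values). The alkaline phosphatase Alpl was higher by 1.55 ± 0.20 (1.34e-05), Agxt, an aminotransferase of glyoxylate, by 1.40 ± 0.20 (3.8e-05) and Cyp1a2 by 1.15 ± 0.20 (4.4e-04). Of glycolysis and gluconeogenesis 6 of 19 genes were higher (6 adjusted over the list alone), with Pfkfb1 at 1.12 ± 0.21 (0.00106) and Ldha at 1.04 ± 0.15 (4.55e-05). Of the respiratory chain 5 of 21 were higher (8 adjusted over the list alone), with Cox5a at 0.69 ± 0.14 (0.00192). Akr7a3, an aflatoxin aldehyde reductase, stood at -1.68 ± 0.23 (3.35e-05) and the decarboxylase Ddc at -1.60 ± 0.19 (7.39e-06). The hydroxysteroid dehydrogenase Akr1c14 was at -1.43 ± 0.17 (4.5e-06) and the glutathione transferase Gstm1 at -1.35 ± 0.21 (1.43e-04). Cyp4a1, a known target of peroxisome proliferators, differed by only 0.27 ± 0.10 (0.127), and Acaa1a, the peroxisomal thiolase, by -0.49 ± 0.38 (0.605).

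In all, 133 features differed at 24 h, 102 of them higher with the proliferators and 31 lower. Camera called 7 of 25 lists. Fatty acid oxidation (adjusted p = 1.47e-12) and the CAR and PXR targets, of which 6 of 9 were lower (7 adjusted over the list alone; median -1.35, 3.49e-10), also passed with an estimated correlation (adjusted p = 0.0121 and 1.96e-04). The respiratory chain (median 0.34, 2.89e-04), glycolysis (0.31, 0.0294), the ribosome (0.25, 1.42e-04; 2 of 32 higher, 3 adjusted over the list alone), glutathione transferases (-0.16, 0.0294; 1 of 11 higher and 3 lower) and amino acid metabolism (0.17, 0.0399; 3 of 26 higher, 3 adjusted over the list alone) did not, with adjusted p = 0.129, 0.138, 0.473, 0.216 and 0.551 with an estimated correlation. Of the features, 91 differed within arrays 50 to 77, which hold every animal, 157 within arrays 82 to 100 (1 Wyeth 14,643 animal) and 193 with the series as a term. Of these 81, 93 and 126 were among the 133. The median of fatty acid oxidation was 0.70 and 0.91 in these series, that of the CAR and PXR targets -1.85 and -1.45, and that of glycolysis -0.01 and 0.40. Without phenobarbital animal 45 the count was 76, and the split was 83 higher and 56 lower without centring and 93 and 69 without floor and tail values.

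**Figure D1:**
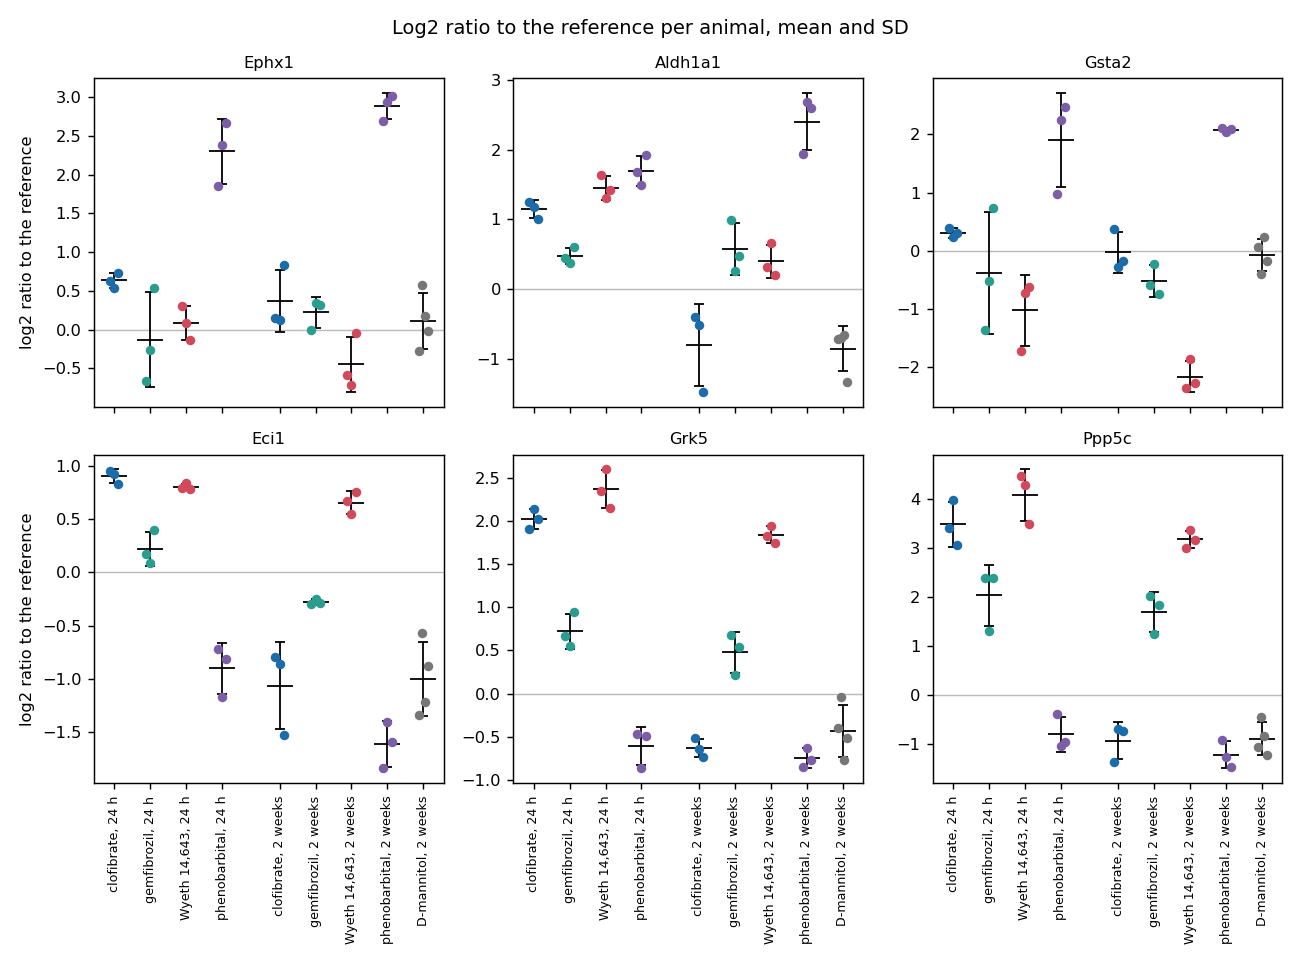
Log2 ratio to the reference of 6 genes (Ephx1, Aldh1a1, Gsta2, Eci1, Grk5 and Ppp5c) in each animal of the 9 groups, with points for animals and bars for the mean and SD. Ephx1 averaged 2.30 at 24 h and 2.88 at 2 weeks with phenobarbital and at most 0.64 in any other group, while Ppp5c averaged 3.47 with clofibrate at 24 h and -0.94 at 2 weeks.

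After 2 weeks phenobarbital livers again held more mRNA of drug-metabolizing enzymes than livers of the proliferators. Ephx1 stood at -2.83 ± 0.23 (n = 9 and 3 animals, adjusted p = 2.7e-08), Gsta2 at -2.98 ± 0.34 (2.16e-06), Akr7a3 at -2.51 ± 0.23 (1.44e-07). Gstm1 was at -2.02 ± 0.21 (6.72e-07) and the retinal dehydrogenase Aldh1a1 at -2.34 ± 0.21 (1.26e-07). The quinone reductase Nqo1, a gene of the oxidative stress list, was at -1.73 ± 0.36 (0.00292). Genes higher with the proliferators included Eci1 at 1.39 ± 0.16 (2.35e-06), the thiolase Acaa2 at 0.97 ± 0.15 (1.25e-04), Acsl1 at 0.89 ± 0.16 (9.41e-04) and Alpl at 1.22 ± 0.20 (2.79e-04). Against the reference Eci1 was at -1.07 with clofibrate and -1.62 with phenobarbital, so its mean difference does not hold alike for each proliferator.

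Of the 9 CAR and PXR targets 7 were lower (7 adjusted over the list alone), and 7 of the 14 genes of fatty acid oxidation were higher (8 adjusted over the list alone), with medians of -2.34 and 0.51. Decr1, a reductase of unsaturated fatty acids, was at 0.91 ± 0.16 (adjusted p = 4.92e-04), and Cpt1a at 0.24 ± 0.19 (0.579). Pvalb, the calcium-binding parvalbumin, was at -2.19 ± 0.22 (5.08e-07), the glutathione transferase Gstm2 at -1.36 ± 0.23 (3.67e-04) and Stmn1, a regulator of microtubules, at -1.16 ± 0.15 (2.25e-05). Secreted proteins were lower in part: apolipoprotein Apoa1 at -1.39 ± 0.29 (0.00321) and complement C3 at -0.97 ± 0.21 (0.0033), although both calls were lost within arrays 137 to 179. Fitted with only the compared groups the call of C3 was lost as well, and with quantile normalization that of Decr1. Cyp4a1 was at -0.15 ± 0.10 (0.519) and Acaa1a at 0.16 ± 0.38 (0.910).

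At 2 weeks 131 features differed, 41 higher and 90 lower. The CAR and PXR targets (camera, adjusted p = 3.04e-12) passed with an estimated correlation as well (adjusted p = 4.6e-05), and fatty acid oxidation (1.06e-07) did not (adjusted p = 0.0963). The other 5 calls were lost with an estimated correlation: glutathione transferases (4 of 11 lower, 4 adjusted over the list alone; 0.00643, then adjusted p = 0.117), acute phase proteins (3 of 18, 5; 0.0128, then 0.512), secreted proteins of the negative acute phase (2 of 10, 5; 0.0473, then 0.732), oxidative stress (5 of 18, 6; 0.0128, then 0.398) and the respiratory chain (0 of 21, 0; 0.0167, then 0.398). The count was 86 within arrays 137 to 179, 152 within arrays 102 to 135 (1 animal each with clofibrate and Wyeth 14,643) and 223 with the series as a term, of which 70, 94 and 126 were among the 131. Both leading lists kept their signs there, with medians of -2.16 and -2.15 for the CAR and PXR targets and 0.64 and 0.42 for fatty acid oxidation. Without phenobarbital animal 58 the count was 87. The split was 69 higher and 86 lower without centring and 12 and 46 with quantile normalization.

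**Figure D2:**
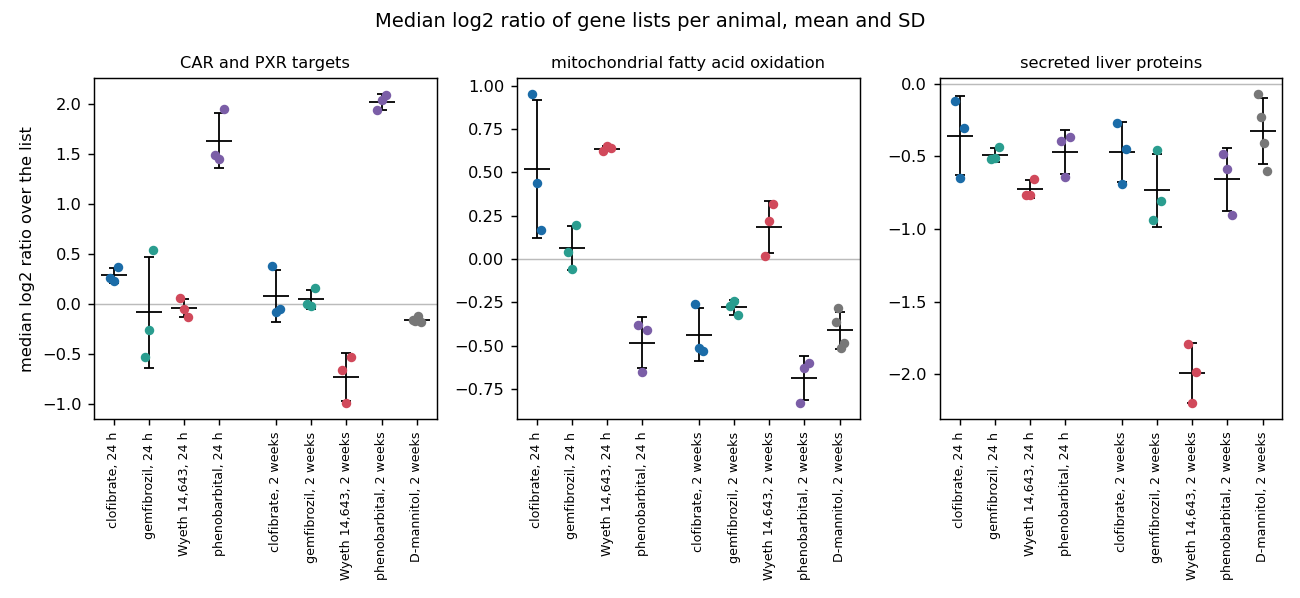
Median log2 ratio to the reference over the genes of 3 lists (CAR and PXR targets, mitochondrial fatty acid oxidation, secreted liver proteins) in each animal of the 9 groups, with points for animals and bars for the mean and SD. CAR and PXR targets averaged 1.63 at 24 h and 2.02 at 2 weeks with phenobarbital, and secreted proteins averaged -1.99 with Wyeth 14,643 at 2 weeks and -0.33 with D-mannitol.

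The difference between the mean of the 3 proliferators and phenobarbital itself changed from 24 h to 2 weeks in 9 features, and all 9 moved down (1 up and 6 down without floor and tail values). Pvalb changed by -1.81 ± 0.31 (adjusted p = 0.00588), Aldh1a1 by -1.67 ± 0.30 (0.00724), Cltb, a clathrin light chain, by -1.07 ± 0.18 (0.00588) and Grk5 by -1.0 ± 0.20 (0.0176). For Grk5, clofibrate minus gemfibrozil was 1.30 at 24 h and -1.11 at 2 weeks, and for Aldh1a1 it was 0.66 and -1.36. The mean change therefore need not hold for each proliferator. Pfkfb1 (-1.33 ± 0.30, 0.0495) and Odc1, the first enzyme of polyamine synthesis (-0.86 ± 0.19, 0.0499), were near the threshold, and in 20 and 24 of their 33 alternatives they did not pass. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, changed by 1.93 ± 0.47 and did not pass (0.0593), but it passed in 7 of 33 alternatives, among them the one without floor and tail values (2.12, adjusted p = 0.0207). Camera called 0 of 25 lists (9 at an unadjusted p under 0.05; fry 3 in 1 direction and 1 in either). No series holds both times, so this change cannot be told apart from the array series. Taking arrays 50 to 77 and 137 to 179 alone, limma called 0 features (70 unadjusted), the other series, with 1 animal in 3 of the groups, 22 and the fit with a series term 30, of which 4 and 8 were among the 9. Without phenobarbital animal 45 of 24 h the count was 3, without animals 57, 58 and 59 of 2 weeks it was 15, 5 and 5, and without clofibrate animal 48 of 2 weeks it was 21. Uncentred values gave 1 higher and 5 lower, and quantile normalization 2 and 27.

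Clofibrate and gemfibrozil are structurally related: clofibrate is the ethyl ester of a chlorophenoxy-isobutyric acid and gemfibrozil a dimethylphenoxy-dimethylpentanoic acid. Doses are not in the labels, so the compounds are compared at matched times and unknown doses. After 24 h, clofibrate livers held more Grk5 mRNA than gemfibrozil livers by 1.30 ± 0.17 (n = 3 and 3, adjusted p = 4.15e-04, 95% interval 0.94 to 1.66) and more Atp1b1, a subunit of the sodium pump, by 1.17 ± 0.19 (0.0021, 0.78 to 1.57). Ppp5c was higher by 1.45 ± 0.33 (0.0133, 0.76 to 2.14), the chaperonin Hspe1 by 0.98 ± 0.18 (0.00642, 0.60 to 1.36), Acaa2 by 0.83 ± 0.18 (0.0125, 0.45 to 1.21). Acsl1 was higher by 0.76 ± 0.20 (0.0215, 0.34 to 1.18) and the urea cycle enzyme Otc by 1.12 ± 0.28 (0.0159, 0.54 to 1.69). Apoa1 was at -1.24 ± 0.36 (0.0308, -1.98 to -0.49). Cyp4a1 did not differ (-0.01, interval -0.28 to 0.26), nor did Cpt1a, the carnitine palmitoyltransferase of liver (-0.18, interval -0.66 to 0.29). Grk5 and Atp1b1 passed in all 15 of their alternatives. The other calls named here were lost in at least 2 of 15, with adjusted p up to 0.0891 for Ppp5c, 0.137 for Hspe1, 0.0811 for Acaa2, 0.181 for Acsl1, 0.112 for Otc and 0.210 for Apoa1.

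In all, 193 features differed between clofibrate and gemfibrozil at 24 h, 159 higher and 34 lower, and this count depended on the setting. It was 23 without centring (10 higher, 13 lower; the median of all features moved by -0.26), 371 with quantile normalization (264 higher, 107 lower; median 0.20) and 73 with both groups fitted alone, and without floor and tail values the split was 136 higher and 87 lower. It was 8 within arrays 50 to 77, 214 within arrays 82 to 100 and 181 with the series as a term, of which 8, 87 and 138 were among the 193. Without clofibrate animal 35 it was 13, and without gemfibrozil animals 36 and 43 it was 59 and 39. On arrays 50, 69 and 73 of clofibrate animal 41 the median used for centring was the repeated value itself. On the gemfibrozil arrays the median lay above the repeated value. Whether this shaped the count or its split was not tested. Camera called 4 lists as higher with clofibrate: the ribosome (10 of 32, 20 adjusted over the list alone; median 0.40, adjusted p = 1.54e-04), fatty acid oxidation (5 of 14, 8; 0.51, 0.0021), amino acid metabolism (6 of 26, 6; 0.52, 0.00242) and oxidative stress (5 of 18, 5; 0.37, 0.0105). With an estimated correlation none passed (adjusted p = 0.486, 0.482, 0.486 and 0.482).

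After 2 weeks, clofibrate and gemfibrozil differed in 13 features, and Ppp5c and Grk5 now had the opposite sign. Ppp5c was at -2.63 ± 0.33 (adjusted p = 1.74e-04, interval -3.31 to -1.94) and Grk5 at -1.11 ± 0.17 (0.00217, -1.47 to -0.75). Aldh1a1 (-1.36 ± 0.26, 0.00993, -1.91 to -0.82), the carnitine transporter Slc22a5 (-0.91 ± 0.19, 0.0208, -1.30 to -0.52) and Ldha (-0.79 ± 0.18, 0.0373, -1.16 to -0.41) were also lower with clofibrate. The glutathione transferase Gstp1 was higher (0.90 ± 0.17, 0.00993, 0.54 to 1.26). Cyp4a1 did not differ (0.05, interval -0.21 to 0.32), and Cpt1a was at -0.79 (interval -1.27 to -0.32) but did not pass over all features (adjusted p = 0.194), although it did in 5 of 15 alternatives. With both groups fitted alone 1 feature passed, with quantile normalization 7 (2 higher, 5 lower). The count was 114 within arrays 137 to 179 (8 of the 13), 2 within arrays 102 to 135 (1 of the 13), where clofibrate has a lone animal assumed to vary like the other groups, and 177 with the series as a term (13 of the 13). Without clofibrate animals 48, 49 and 50 the count was 20, 6 and 6, and without gemfibrozil animals 54, 55 and 56 it was 5, 7 and 6. Camera called the acute phase list (median 0.33, 0.00216), with 0 of 18 genes past by limma (0 adjusted over the list alone), and it was lost with an estimated correlation (adjusted p = 0.584). The difference between the 24 h and 2 week contrasts of this pair was not tested.

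Wyeth 14,643 after 24 h differed from both fibrates in Slc2a2, Serpina3n, Cyp1a2 and Psmc2. The glucose transporter Slc2a2 was higher with clofibrate by 1.80 ± 0.28 (adjusted p = 0.00174) and with gemfibrozil by 1.62 ± 0.28 (9.79e-04), and Serpina3n, an acute phase protease inhibitor, by 1.34 ± 0.26 (0.00477) and 1.48 ± 0.26 (9.05e-04). Cyp1a2 was lower with both, at -1.37 ± 0.24 (0.00337) and -1.47 ± 0.24 (6.85e-04), as was the proteasome subunit Psmc2, at -1.36 ± 0.24 (0.00276) and -1.22 ± 0.24 (0.00257). Selenop, a selenium carrier of plasma (1.28 ± 0.22, 0.00267), and Id1, an inhibitor of transcription factors (-1.41 ± 0.21, 0.00146), were among 42 features that differed between clofibrate and Wyeth 14,643. With gemfibrozil, Grk5 (-1.65 ± 0.17, 3.93e-06), the glutamate receptor Gria3 (-1.77 ± 0.13, 1.79e-08), Cpt2 (-1.13 ± 0.15, 5.97e-05), Hspe1 (-1.34 ± 0.18, 9.52e-05) and Ppp5c (-2.05 ± 0.33, 5.73e-04; -1.58 without floor and tail values) were lower than with Wyeth 14,643, among 172 features. Grk5, Gria3 and Cpt2 passed in all 15 of their alternatives. The other gemfibrozil calls named here were lost in 1 or 2 of 15, and those of clofibrate in at least 1.

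The 42 features of clofibrate split into 18 higher and 24 lower, and the 172 of gemfibrozil into 29 and 143. Within arrays 50 to 77, 82 to 100 and with the series as a term the counts were 24, 275 and 132 for clofibrate (24, 18 and 40 among the 42) and 52, 152 and 169 for gemfibrozil (51, 36 and 125 among the 172). Arrays 82 to 100 hold a lone Wyeth 14,643 animal, assumed to vary like the other groups, so their counts of 275 and 152 rest on that animal. With both groups fitted alone limma called 0 features for clofibrate (178 unadjusted) and 51 for gemfibrozil. Without clofibrate animals 35 and 41 the first count was 24 and 67, and without gemfibrozil animal 43 and Wyeth 14,643 animal 16 the second was 105 and 97. The split was 30 higher and 21 lower with quantile normalization and 58 and 40 without floor and tail values for clofibrate. For gemfibrozil it was 44 and 54 uncentred, 49 and 130 quantile-normalized and 64 and 101 without floor and tail values. Camera called 5 and 3 lists. For clofibrate these were amino acid metabolism (2 of 26 higher, 8 adjusted over the list alone; adjusted p = 5.72e-06), acute phase (1 of 18, 2; 9.82e-05), secreted proteins (0 of 10, 1; 9.82e-05), the proteasome (1 of 9 lower, 1; 0.038) and sex- and growth-hormone-dependent genes (1 of 8 higher, 2; 0.038). For gemfibrozil they were fatty acid oxidation (7 of 14 lower, 11; 7.84e-05), the ribosome (7 of 32 lower, 13; 3.97e-04) and the proteasome (6 of 9 lower, 6; 0.00122). None passed with an estimated correlation (adjusted p = 0.353 to 0.371 for clofibrate and 0.330 to 0.835 for gemfibrozil).

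After 2 weeks Wyeth 14,643 livers held less mRNA of the same 8 of 10 secreted liver proteins than livers of each fibrate, though with quantile normalization limma called 1 of the 10 against clofibrate and 0 against gemfibrozil. By camera the lists of secreted proteins, amino acid metabolism and glutathione transferases were lower with Wyeth 14,643 than with each fibrate and those of fatty acid oxidation and the ribosome higher, but none of these calls passed with an estimated correlation. Clofibrate exceeded Wyeth 14,643 in Hsd11b1, which activates glucocorticoids, by 3.15 ± 0.26 (adjusted p = 3.05e-08; 2.88 without floor and tail values) and in the apolipoprotein Apoc3 by 3.06 ± 0.27 (7.86e-08; 2.85). It was higher in Slc2a2 by 2.89 ± 0.28 (2.27e-07) and in Ass1, of the urea cycle, by 2.54 ± 0.32 (5.26e-06). Gemfibrozil exceeded it in Apoc3 by 2.61 ± 0.27 (1.46e-06; 2.45), Slc2a2 by 2.50 ± 0.28 (3.58e-06), Pvalb by 2.40 ± 0.27 (3.58e-06) and the thyroid hormone carrier Ttr by 2.19 ± 0.28 (1.08e-05). The desaturase Scd2 was lower than with Wyeth 14,643, at -3.58 ± 0.33 with clofibrate (9.17e-08) and -2.73 ± 0.33 with gemfibrozil (7.31e-06), and Eci1 was at -1.73 ± 0.19 (1.17e-06) and -0.94 ± 0.19 (0.00197).

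Of 10 secreted proteins 8 were higher with clofibrate (9 adjusted over the list alone; median 1.31, adjusted p = 9.54e-07) and 8 with gemfibrozil (8; 1.06, 1.57e-07). Higher were 13 of 18 acute phase proteins (13; 1.04, 5.48e-06) and 8 (10; 0.68, 2.75e-04), and 7 of 11 glutathione transferases (8; 1.15, 0.00351) and 5 (5; 0.96, 0.00749), in the same order. Of 26 genes of amino acid metabolism 13 were higher and 1 lower with clofibrate (14 and 1; 0.78, 1.75e-04) and 7 and 1 with gemfibrozil (11 and 1; 0.55, 5.6e-04). Of 14 genes of fatty acid oxidation 8 were lower with clofibrate (8; -0.66, 9.48e-05) and 5 with gemfibrozil (6; -0.40, 2.75e-04). Of 32 ribosomal proteins 13 were lower (14; -0.42, 1.94e-06) and 16 (18; -0.44, 6.66e-09). Camera called 9 lists in each comparison and 0 with an estimated correlation, where the adjusted p of these lists ran from 0.157 to 0.242 for clofibrate and from 0.203 to 0.239 for gemfibrozil (12 and 10 lists passed unadjusted, and fry called 15 and 17). In all, 430 features differed from clofibrate (280 higher, 150 lower) and 279 from gemfibrozil (180 higher, 99 lower). Within arrays 137 to 179, 102 to 135 and with the series as a term the counts were 307, 363 and 534 (285, 205 and 417 among the 430) and 245, 340 and 376 (139, 154 and 252 among the 279). Arrays 102 to 135 hold 1 clofibrate and 1 Wyeth 14,643 animal, assumed to vary like the other groups, so 363 compares 1 animal with 1 and 340 compares 3 with 1. Quantile normalization left 75 features for clofibrate (34 higher, 41 lower) and 0 by limma for gemfibrozil (180 unadjusted), and fits on both groups alone 164 and 71. Without centring the splits were 199 higher and 223 lower, and 163 and 156. All calls named here for gemfibrozil were lost with quantile normalization, where Ttr differed by 1.02 (adjusted p = 0.194).

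Against D-mannitol, given for 2 weeks, the compounds differed widely in how many features changed: 447 with Wyeth 14,643, 34 with phenobarbital, 8 with gemfibrozil and 2 with clofibrate. The labels do not give the vehicle of D-mannitol, and no group had vehicle alone, so vehicles may differ in these comparisons. Wyeth 14,643 raised Ppp5c by 4.07 ± 0.31 (n = 3 and 4, adjusted p = 3.22e-09), Scd2 by 3.82 ± 0.31 (7.2e-09), Eci1 by 1.66 ± 0.18 (5.1e-07) and Acat1 by 1.55 ± 0.24 (4.86e-05). Among messenger RNAs of secreted proteins, Apoc3 fell by 3.43 ± 0.26 (2.91e-09; by 3.18 without floor and tail values), the complement protease C1s by 3.69 ± 0.45 (1.89e-06) and Apoa1 by 2.70 ± 0.33 (2.61e-06). Ttr fell by 2.58 ± 0.26 (1.56e-07), transferrin Tf by 2.21 ± 0.23 (2.75e-07) and C3 by 1.94 ± 0.24 (1.96e-06). So did Hsd11b1, by 3.46 ± 0.24 (1.78e-09; by 3.16 without floor and tail values) and Slc2a2, by 2.84 ± 0.27 (7.41e-08). The ornithine enzyme Oat fell by 3.30 ± 0.36 (5.21e-07) and the bile acid transporter Slc10a1 by 1.91 ± 0.23 (1.54e-06).

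The 447 features of Wyeth 14,643 were 156 higher and 291 lower. Camera called 8 lists, and with an estimated correlation 0 of them (adjusted p = 0.237 to 0.376; 10 lists passed unadjusted, and fry called 17). Of the secreted proteins 9 of 10 were lower (9 adjusted over the list alone; median -1.78, adjusted p = 8.15e-09) and of the acute phase 13 of 18 (13; -1.05, 1.24e-06). Lower too were 11 of 26 of amino acid metabolism (11; -0.57, 0.00242), 6 of 8 sex- and growth-hormone-dependent genes (6; -1.15, 0.00242) and 7 of 11 glutathione transferases (7; -0.84, 0.0198). Higher were 15 of 32 ribosomal proteins (19; 0.46, 2.22e-06), 8 of 14 genes of fatty acid oxidation (8; 0.55, 0.00158) and 2 of 6 of fatty acid synthesis, Scd and Scd2 (2; 1.59, 0.0337). Within arrays 137 to 179, 102 to 135 and with the series as a term 281, 579 and 479 features differed (259, 301 and 393 among the 447), and the median of fatty acid oxidation was 0.79, 0.23 and 0.64. The values of arrays 102 to 135 rest on a lone Wyeth 14,643 animal, assumed to vary like the other groups. Quantile normalization gave 118 features (56 higher, 62 lower) and uncentred values 236 higher and 216 lower, with the median of all features at 0.30. With array 130 turned 431 features differed, and without it 432.

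Phenobarbital raised drug-metabolizing enzymes above D-mannitol: the carboxylesterase Ces2c by 3.96 ± 0.43 (n = 3 and 4, adjusted p = 4.45e-06; 3.65 without floor and tail values), Aldh1a1 by 3.25 ± 0.24 (1.14e-08), Ephx1 by 2.77 ± 0.26 (6.11e-07). It raised Akr7a3 by 2.19 ± 0.27 (1.23e-05), Gsta2 by 2.15 ± 0.38 (0.002), Ddc by 1.89 ± 0.22 (9.5e-06) and Gstm1 by 1.42 ± 0.24 (0.00112). Glutamine synthetase, Glul, fell by 1.33 ± 0.26 (0.00441). Of 34 features 26 were higher and 8 lower, and 7 of the 9 CAR and PXR targets were higher (7 adjusted over the list alone; median 2.15, camera adjusted p = 1.05e-15, and adjusted p = 7.53e-06 with an estimated correlation). Its 7 other list calls were lost with an estimated correlation, among them fatty acid oxidation (0 of 14 lower, 6 adjusted over the list alone; median -0.31, 1.01e-04, then adjusted p = 0.250), secreted proteins (1 of 10 lower, 3; -0.39, 7.23e-05, then 0.325) and glutathione transferases (3 of 11 higher, 4; 0.39, 0.0184, then 0.250). Within arrays 137 to 179, 102 to 135 and with the series as a term 29, 34 and 129 features differed (21, 27 and 34 among the 34), and the median of the CAR and PXR targets was 2.11, 2.10 and 2.13. Without phenobarbital animal 59 the count was 21, with array 130 turned 41 and without it 36. Uncentred values gave 30 higher and 23 lower, values without floor and tail 33 and 21, and fits on both groups alone 20 features.

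Gemfibrozil raised Ppp5c above D-mannitol by 2.59 ± 0.31 (adjusted p = 7.48e-05), which passed in all 18 alternatives. It raised Aldh1a1 by 1.42 ± 0.24 (0.0042), Grk5 by 0.91 ± 0.16 (0.0048) and Pdpn, a membrane glycoprotein, by 0.67 ± 0.12 (0.0042). Apcs, a pentraxin of plasma, fell by 0.84 ± 0.16 (0.00925). Calls of Aldh1a1, Grk5, Pdpn and Apcs were lost in 2, 4, 5 and 4 of 18 alternatives, that of Pdpn also with array 130 turned. Of 8 features 5 were higher and 3 lower. Clofibrate differed in 2, Lyz2, the lysozyme of macrophages (0.97 ± 0.19, 0.0362), and Ldha (-0.93 ± 0.17, 0.0302), which were lost in 7 and 6 of 18 alternatives. Cpt1a (-0.99 ± 0.21) and Apoa1 (-1.54 ± 0.33) did not pass with clofibrate (0.0692 for both), but passed in 7 and 6 of 18 alternatives, among them the one without floor and tail values (-0.96 and -1.65, adjusted p = 0.0156 and 0.0115). Cyp4a1 was at -0.16 ± 0.12 (0.670) with gemfibrozil. Camera called acute phase proteins (1 of 18 lower, 2 adjusted over the list alone; median -0.41, 1.23e-05), secreted proteins (0 of 10, 4; -0.40, 1.23e-05) and fatty acid synthesis (0 of 6, 2; 0.65, 0.0423) for gemfibrozil, and secreted proteins for clofibrate (0 of 10, 1; 0.0251). All were lost with an estimated correlation (adjusted p = 0.422 for gemfibrozil and 0.956 for clofibrate). Within arrays 137 to 179, 102 to 135 and with the series as a term 16, 19 and 137 features differed for gemfibrozil (6, 5 and 8 among the 8) and 15, 0 (66 unadjusted) and 44 for clofibrate (1, 0 and 2 among the 2), where arrays 102 to 135 hold a lone clofibrate animal assumed to vary like the other groups. Turning array 130 gave 7 and 3, and leaving it out 8 and 2. Without gemfibrozil animals 54, 55 and 56 its count was 3, 34 and 3, and without clofibrate animals 48 and 49 and D-mannitol animals 60 and 61 the other count was 13, 0, 1 and 0 (82 and 83 unadjusted at 0). With the groups fitted alone limma called 5 and 0 features (76 unadjusted for clofibrate), and quantile normalization 22 and 6.

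**Figure D3:**
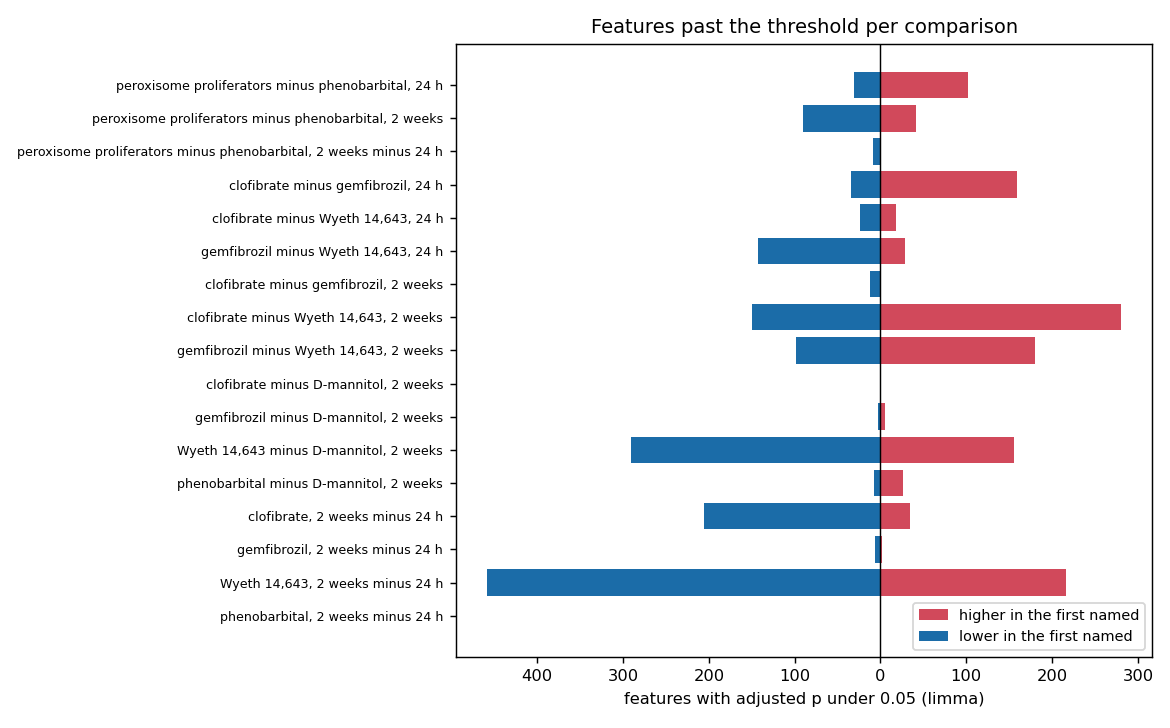
Features past an adjusted p of 0.05 in 17 comparisons between groups, with bars to the right for higher and to the left for lower features. Wyeth 14,643 against D-mannitol held 156 higher and 291 lower, and clofibrate against D-mannitol 1 and 1.

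Against the reference at 24 h the clofibrate livers differed in 164 features (127 higher, 37 lower), gemfibrozil in 523 (249 and 274), Wyeth 14,643 in 421 (267 and 154) and phenobarbital in 383 (166 and 217). Ppp5c was at 3.47 ± 0.23 with clofibrate and 4.07 ± 0.23 with Wyeth 14,643 (3.60 without floor and tail values), and Grk5 at 2.02 ± 0.12 with clofibrate (adjusted p = 4.01e-10). With Wyeth 14,643 the metallothionein Mt2A was at -3.96 ± 0.39 (-3.70 without floor and tail values), Slc2a2 at -2.25 ± 0.20 and Ass1 at -1.89 ± 0.23. Phenobarbital livers were at 2.63 ± 0.33 for Ces2c, 2.30 ± 0.20 for Ephx1, -1.91 ± 0.20 for Glul and -1.48 ± 0.14 for Pc, the pyruvate carboxylase. Glul was at -1.17 ± 0.20 and Apoc4 at -1.12 ± 0.20 with gemfibrozil. At 2 weeks 605 features differed with clofibrate (304 higher, 301 lower), 880 with gemfibrozil (451 and 429), 1100 with Wyeth 14,643 (591 and 509), 712 with phenobarbital (375 and 337) and 610 with D-mannitol (295 and 315). D-mannitol livers were at -1.0 ± 0.12 for Eci1 and -1.34 ± 0.34 for Mt2A.

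These counts against the reference rest on the pooled spread and on centring. With each group fitted alone they were 3, 148, 3 and 0 (554 unadjusted by limma) at 24 h in the order clofibrate, gemfibrozil, Wyeth 14,643 and phenobarbital, and 0 (404 unadjusted), 44, 419, 278 and 3 at 2 weeks, with D-mannitol last. Without centring the higher and lower counts were 82 and 91, 322 and 160, 223 and 208, and 200 and 166 at 24 h, and 394 and 137, 606 and 157, 889 and 296, 518 and 190, and 386 and 113 at 2 weeks, with medians of all features at -0.02, 0.28, 0.16 and 0.25, and at 0.31, 0.40, 0.55, 0.35 and 0.26. With quantile normalization they were 579 and 31, 518 and 119, 570 and 78, and 566 and 115 at 24 h, and 526 and 103, 488 and 126, 546 and 129, 524 and 103, and 536 and 100 at 2 weeks. Without floor and tail values they were 145 and 123, 401 and 336, 315 and 295, and 331 and 299 at 24 h, and 123 and 240, 268 and 327, 527 and 447, 207 and 295, and 290 and 304 at 2 weeks. Medians of all features with quantile normalization were 0.47, 0.31, 0.48 and 0.45, and 0.36, 0.27, 0.29, 0.42 and 0.34. Single animals moved these counts too: at 24 h to 78 without clofibrate animal 35, to 321, 233 and 334 without gemfibrozil animals 36, 43 and 44, and to 237 and 105 without phenobarbital animals 37 and 45. At 2 weeks they fell to 119 and 115 without clofibrate animals 49 and 50, to 319 and 467 without gemfibrozil animals 54 and 56, to 315 without phenobarbital animal 59 and to 249 without D-mannitol animal 63. D-mannitol had 683 features with array 130 turned and 704 without it.

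Calls against the reference were shared between compounds. At 24 h clofibrate and Wyeth 14,643 shared 125 features in the same direction and 0 in the opposite one, with 23.4 for independent lists, and gemfibrozil and phenobarbital shared 193 and 5 (59.7). Clofibrate and gemfibrozil shared 45 and 11 (24.7), clofibrate and phenobarbital 38 and 23 (17.2), gemfibrozil and Wyeth 14,643 153 and 8 (64.3), and Wyeth 14,643 and phenobarbital 119 and 38 (46). Both pairs named first also lie mostly in 1 array series each, with 7 and 8 of 9 arrays among 50 to 77 for clofibrate and Wyeth 14,643 and 6 of 9 among 82 to 100 for gemfibrozil and phenobarbital. Within arrays 50 to 77 alone, clofibrate and Wyeth 14,643 shared 87 (12.4 for independent lists; correlation 0.483), and gemfibrozil and phenobarbital 41 (6.16; 0.460). The correlation of the ratios across features ran from 0.176 for clofibrate and phenobarbital to 0.733 for gemfibrozil and phenobarbital, with covariances of 0.0562 and 0.556. Simulated groups without an effect that share a reference gave 0.749 and 0.750, with covariances of 0.599 and 0.601. At 2 weeks from 374 (clofibrate and phenobarbital, 128 for independent lists) to 683 (gemfibrozil and Wyeth 14,643, 287) were shared in the same direction, with correlations from 0.811 to 0.893 and covariances from 0.938 to 1.93 (0.749 to 0.752 and 0.596 to 0.606 simulated). The spread of the reference was not measured. At 24 h every correlation lay below the simulated one, so all of each excess may come from the shared reference, and at 2 weeks an unknown part, up to all of it. The simulated values rest on an assumed spread of the reference, so they cannot set the 2 times apart in this respect. Against D-mannitol all 8 features of gemfibrozil were called in the same direction with Wyeth 14,643 (0.979 for independent lists). The ratios of this pair had a covariance of 0.324 with shared D-mannitol animals (0.151 simulated without effect) and 0.131 when the 4 animals were split between them, with split correlations from -0.055 to 0.426. It was the highest of the 6 pairs of compounds. With the animals split, the covariance was -0.134 for clofibrate and Wyeth 14,643 (correlation 0.0995 with shared animals, 0.432 simulated) and from -0.0333 to 0.0269 for the other 4 pairs.

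Between 24 h and 2 weeks 240 features differed with clofibrate (34 higher, 206 lower), 8 with gemfibrozil (2 and 6), 674 with Wyeth 14,643 (216 and 458) and 0 with phenobarbital by limma (172 unadjusted; 54 with all arrays and the animal as a block, 2 with quantile normalization, 6 with both groups fitted alone). With clofibrate, the difference of 2 weeks from 24 h was -4.41 ± 0.33 for Ppp5c (n = 3 and 3, adjusted p = 1.11e-08), -2.65 ± 0.17 for Grk5 (1.67e-09), -1.97 ± 0.19 for Eci1 (5.73e-07) and -1.31 ± 0.18 for Ldha (4.02e-05). With Wyeth 14,643, Scd2 was higher at 2 weeks by 3.26 ± 0.33 (8.88e-07). Lower were Oat (-3.42 ± 0.39, 3.4e-06), Hsd11b1 (-2.96 ± 0.26, 2.24e-07; -2.46 without floor and tail values) and Apoc3 (-2.96 ± 0.27, 2.51e-07; -2.51). With gemfibrozil the lactate transporter Slc16a1 was at -2.79 ± 0.54 (0.0274) and Dpys, of pyrimidine breakdown, at -1.74 ± 0.33 (0.0274), which were lost in 5 and 6 of 12 alternatives.

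Time and array series cannot be told apart in these comparisons, since no series holds both times. Camera called fatty acid oxidation as lower at 2 weeks with clofibrate (10 of 14, 12 adjusted over the list alone; median -0.93, adjusted p = 1.35e-09), gemfibrozil (1 of 14, 2; -0.27, 2.43e-04) and phenobarbital (0 of 14, 4; -0.24, 2.36e-04), and the secreted proteins with Wyeth 14,643 (9 of 10, 9; -1.23, 2.09e-04). These were lost with an estimated correlation (adjusted p = 0.0754, 0.682, 0.648 and 0.522). Also called as lower were the ribosome (13 of 32, 20; -0.45, 3.58e-06) and the proteasome (4 of 9, 7; -0.60, 0.0203) with clofibrate, and the secreted proteins with phenobarbital (0 of 10, 2; -0.26, 0.0308), which were lost as well (adjusted p = 0.701, 0.701 and 0.648). Single animals moved the clofibrate count to 134 (24 h animal 35), 480, 118 and 120 (2 week animals 48, 49 and 50), and that of gemfibrozil to 1, 4 and 0 (24 h animals 36, 43 and 44) and 0, 4 and 0 (2 week animals 54, 55 and 56), where limma had 154, 113 and 140 unadjusted at 0. For phenobarbital the count was 2, 2 and 4 without 24 h animals 37 and 45 and 2 week animal 57. Uncentred splits were 54 higher and 67 lower for clofibrate, 4 and 2 for gemfibrozil and 335 and 140 for Wyeth 14,643, with medians of all features at 0.34, 0.10 and 0.30. Quantile normalization gave 96 and 294, 2 and 0, and 50 and 150.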

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

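Tests of explanations and all values by array series, without floor and tail values or with array 130 turned were chosen only after the results were seen; the comparison of 1 animal with the rest of its group, the tests of the change between times and the other splits of the animals were not.

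In the group of 4 D-mannitol animals, the only one large enough to test, 4 of 70 measures had 1 animal far from the others, and chance alone gives about 1 in 20. G6pc1, the glucose-6-phosphatase of liver, was at -2.21 in animal 62 and at -0.82 to -0.80 in the others, a gap of 0.985 of the whole range. Aldh1a1 was at -1.33 in animal 63 and at -0.72 to -0.65 in the others (0.901). The median over genes of glycolysis and gluconeogenesis was -0.47 in animal 63 and -0.18 to -0.13 in the others (0.852), and that over peroxisomal and microsomal fatty acid oxidation was -0.12 and -0.08 to -0.07 (0.839).

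The difference between the mean of the 3 peroxisome proliferators and phenobarbital was not the same at 24 h and 2 weeks, by limma's test of the change, in 9 features. Those were Pvalb (-1.81), Aldh1a1 (-1.67), Pfkfb1 (-1.33), Cltb (-1.07), Grk5 (-0.998), Odc1 (-0.86), Suclg1 (-0.70) and 2 probes without a gene symbol (-2.22 and -0.87), where Suclg1 and the probes were taken because they passed and not by the rule for named genes. Of 100 splits of the animals within each time, 3 gave at least 9 features, the real one included. The highest other split gave 234, several times the real count, which points to a structure of the samples. Such splits are no measure of chance, so they cannot decide whether chance gave the 9 features. No array series holds both times, and time and series cannot be told apart here.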

How the results depend on the processing

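Alternatives chosen after the data were seen were those without floor and tail values, by array series (shared calls included), with the series as a term and with array 130 turned or left out. None of the 230 signed gene values checked for the text reversed in any alternative run. Other genes that the naming rule chose did reverse, such as Hap1 with clofibrate against the reference at 2 weeks, from 3.73 to -0.07 without floor and tail values. Of 217 named gene values past the threshold, 132 were lost in at least 1 alternative: 85 with only the compared groups in the fit, 55 with quantile normalization, 12 without centring, 4 without floor and tail values, 30 and 51 within single array series (the latter with lone animals in 3 groups), and 1 with array 130 turned. Another 5 passed in at least 1 alternative, and leaving out 1 animal ended 152 calls over all genes and animals. Counts with each probe on its own and with only features that have a value on every array stayed within 1.5 times in all 26 comparisons, as did the 5 with D-mannitol when array 130 was turned or left out. The cause was not tested for any count below, except that fits on the compared groups alone have fewer animals for the spread and single series fewer arrays. No paired analysis was possible because the groups share no animal numbers.

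Without centring 23 features differed between clofibrate and gemfibrozil at 24 h (193 with centring), 98 between gemfibrozil and Wyeth 14,643 at 24 h (172), 4, 23 and 53 between clofibrate, gemfibrozil and phenobarbital and D-mannitol (2, 8 and 34) and 121 between times with clofibrate (240). Shared calls at 24 h were 79 for clofibrate and gemfibrozil (45) and 68 for clofibrate and phenobarbital (38).

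Quantile normalization gave, against the reference, 610, 648 and 681 features at 24 h with clofibrate, Wyeth 14,643 and phenobarbital and 675 at 2 weeks with Wyeth 14,643. It gave 58 for the proliferators against phenobarbital at 2 weeks and 29 for the change between times. For clofibrate and gemfibrozil it gave 371 at 24 h and 7 at 2 weeks, and at 2 weeks 75 for clofibrate and 0 by limma (180 unadjusted) for gemfibrozil against Wyeth 14,643. Against D-mannitol the counts were 6, 22 and 118 with clofibrate, gemfibrozil and Wyeth 14,643, and between times 390, 2, 200 and 2 with clofibrate, gemfibrozil, Wyeth 14,643 and phenobarbital.

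With all arrays and the animal as a random block 259 features differed from the reference with clofibrate at 24 h, 219 and 224 between proliferators and phenobarbital at 24 h and 2 weeks and 63 in the change. Counts were 306 and 62 for clofibrate and gemfibrozil at 24 h and 2 weeks, 108 and 265 for clofibrate and gemfibrozil against Wyeth 14,643 at 24 h, 30, 103 and 110 for clofibrate, gemfibrozil and phenobarbital against D-mannitol, and 47 and 54 between times with gemfibrozil and phenobarbital.

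With only the compared groups in the fit, the counts against the reference were 3, 148, 3 and 0 at 24 h with clofibrate, gemfibrozil, Wyeth 14,643 and phenobarbital (554 unadjusted in limma at 0), and 0, 44, 419, 278 and 3 at 2 weeks with D-mannitol last (404 unadjusted at 0). The proliferators against phenobarbital at 2 weeks gave 78. Clofibrate and gemfibrozil gave 73 and 1 at 24 h and 2 weeks, clofibrate and Wyeth 14,643 0 (178 unadjusted) and 164, and gemfibrozil and Wyeth 14,643 51 and 71. Against D-mannitol they were 0 (76 unadjusted), 5 and 20 with clofibrate, gemfibrozil and phenobarbital, and between times 22, 5, 285 and 6 with clofibrate, gemfibrozil, Wyeth 14,643 and phenobarbital.

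Without floor and tail values 268, 630 and 363 features differed from the reference with clofibrate at 24 h, phenobarbital at 24 h and clofibrate at 2 weeks, 98 between clofibrate and Wyeth 14,643 at 24 h, 4, 28 and 54 between clofibrate, gemfibrozil and phenobarbital and D-mannitol, and 152 and 333 between times with clofibrate and Wyeth 14,643.

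Within arrays 50 to 77 and 137 to 179, 148 and 145 features differed from the reference with gemfibrozil and phenobarbital at 24 h and 215 with clofibrate at 2 weeks, 86 between the proliferators and phenobarbital at 2 weeks and 0 in the change (70 unadjusted in limma). Clofibrate and gemfibrozil gave 8 and 114 at 24 h and 2 weeks, clofibrate and Wyeth 14,643 24 and gemfibrozil and Wyeth 14,643 52 at 24 h, and clofibrate, gemfibrozil and Wyeth 14,643 against D-mannitol 15, 16 and 281. Shared calls were 27 for clofibrate and gemfibrozil, 19 for clofibrate and phenobarbital, 68 for gemfibrozil and Wyeth 14,643, 41 for gemfibrozil and phenobarbital and 54 for Wyeth 14,643 and phenobarbital at 24 h, and at 2 weeks 186, 132 and 169 for clofibrate with gemfibrozil, Wyeth 14,643 and phenobarbital and 845 for gemfibrozil and phenobarbital.

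Wyeth 14,643 at either time and clofibrate at 2 weeks have a lone animal in arrays 82 to 100 and 102 to 135, assumed to vary like the other groups. There 41 and 662 features differed from the reference with clofibrate and phenobarbital at 24 h and 2, 256, 721, 241 and 19 at 2 weeks with clofibrate, gemfibrozil, Wyeth 14,643, phenobarbital and D-mannitol. The change between times gave 22, clofibrate against Wyeth 14,643 at 24 h 275, clofibrate against gemfibrozil at 2 weeks 2, and clofibrate and gemfibrozil against D-mannitol 0 (66 unadjusted) and 19. With the series as a term the counts were 223 for the proliferators against phenobarbital at 2 weeks, 30 for the change, 132 for clofibrate and Wyeth 14,643 at 24 h, 177 for clofibrate and gemfibrozil at 2 weeks, and 44, 137 and 129 for clofibrate, gemfibrozil and phenobarbital against D-mannitol. These come from a fit on all arrays with the animal as a random block, so they do not show the series alone.

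Of 650 list tests 129 passed with camera, 7 with an estimated correlation, 241 with fry in 1 direction and 315 with fry in either. The difference in resemblance of animals at 2 weeks (0.0270) stayed about as large with the more variable features (0.0271) and within 1 array series (0.0285), but the exact permutation p rose above 0.05 (0.0710 and 0.0841). With a threshold of 0.01 the shared calls at 24 h fell to 16 for clofibrate and gemfibrozil, 66 for clofibrate and Wyeth 14,643, 18 for clofibrate and phenobarbital, 67 for gemfibrozil and Wyeth 14,643, 76 for gemfibrozil and phenobarbital and 52 for Wyeth 14,643 and phenobarbital, and at 2 weeks, in the same order, to 134, 109, 107, 366, 227 and 244.

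Leaving out 1 animal at a time gave 78 to 128, 233 to 334, 309 to 323 and 105 to 349 features against the reference at 24 h with clofibrate, gemfibrozil, Wyeth 14,643 and phenobarbital. At 2 weeks it gave 115 to 763, 319 to 888, 874 to 1065 and 315 to 546, and 249 to 656 with D-mannitol. The proliferators against phenobarbital had 76 to 140 at 24 h, 87 to 153 at 2 weeks and 3 to 21 in the change. At 24 h clofibrate and gemfibrozil had 13 to 189, clofibrate and Wyeth 14,643 24 to 67, and gemfibrozil and Wyeth 14,643 97 to 158, and at 2 weeks 5 to 20, 351 to 502 and 218 to 282. Against D-mannitol clofibrate had 0 to 13 (82 and 83 unadjusted in limma at 0), gemfibrozil 3 to 34, Wyeth 14,643 350 to 529 and phenobarbital 21 to 40. Between times clofibrate had 118 to 480, gemfibrozil 0 to 4 (113 to 154 unadjusted at 0), Wyeth 14,643 498 to 756 and phenobarbital 0 to 4 (141 to 170 unadjusted at 0).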

Other observations

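The tests that weigh the 3 patterns below were all chosen after the results were seen, as were the values by array series; the splits of the animals and the gene lists were fixed earlier.

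Of 7 measured markers of liver macrophages, 5 were lower and 1 was higher after 2 weeks of Wyeth 14,643 than with D-mannitol (5 and 1 adjusted over the list alone), and the list did not pass (median -0.61, adjusted p = 0.0875). Against clofibrate, 4 were higher with clofibrate (5 adjusted over the list alone; median 0.86, camera adjusted p = 0.0353, and adjusted p = 0.157 with an estimated correlation). The median over the 7 was -0.74 ± 0.03 (SD, n = 3) with Wyeth 14,643 and -0.10 ± 0.11 (n = 4) with D-mannitol. Ctss, a lysosomal protease of macrophages, stood at -1.20 ± 0.21 against D-mannitol (adjusted p = 1.49e-04; 0.230 with quantile normalization, where the difference was -0.54), and Lyz2, the 1 higher marker, at 0.54 ± 0.19 (0.0393), a value looked up after the list was seen. Stellate cell and fibroblast markers (0 of 18 higher and 4 lower, 4 adjusted over the list alone; median -0.04, adjusted p = 0.524) and lymphocyte, neutrophil and mast cell markers (0 of 7 past by limma, 0 adjusted over the list alone; median 0.24, 0.523) did not pass as lists.

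Several groups of liver genes did not pass as lists with Wyeth 14,643 against D-mannitol. Of 14 genes of peroxisomal and microsomal fatty acid oxidation 1 was higher and 3 were lower (1 and 3 adjusted over the list alone; median -0.16, adjusted p = 0.580), and of 12 genes of the cell cycle and DNA synthesis 2 were higher (0 adjusted over the list alone; 0.52, 0.198). Cholesterol and bile acid metabolism had 5 of 11 lower (5; -0.27, 0.198) and fatty acid uptake and lipoproteins 3 of 14 higher and 5 lower (5 and 6; -0.28, 0.322). Single genes outside these lists moved far. Asns, which makes asparagine, was higher by 4.05 ± 1.00 (adjusted p = 0.00395). Of its values 33.3% stood at the floor or beyond 4 on the centred log2 scale, and without floor and tail values the difference was 2.53. The growth factor Igf1 fell by 1.31 ± 0.30 (0.00237). Both calls were lost in 1 of 18 alternatives, with adjusted p of 0.601 and 0.189.

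Few features differed between clofibrate and D-mannitol at 2 weeks (2) and many between Wyeth 14,643 and D-mannitol (447). Whether a larger spread between the clofibrate animals hid a like change could not be decided. Both counts used the same pooled spread (median standard error 0.327 in each), so the error of the test was not larger for clofibrate. Whether the spread of the clofibrate animals moved their means was not tested. With the same animals 8 genes of mitochondrial fatty acid oxidation were lower than with Wyeth 14,643. That comparison used a spread pooled over the 9 groups, so the clofibrate animals' own spread was not tested. These animals correlated at 0.60 with each other, the lowest value within a group at 2 weeks. The count against D-mannitol was 13 without clofibrate animal 48 and 0 without clofibrate animal 49. The tables argue against array series as the whole cause. Within the series that holds every animal the counts were 15 and 281, and with the series as a term, in a fit on all arrays, 44 and 479. The clofibrate count was at most 9.19% of that for Wyeth 14,643. A smaller response to clofibrate after 2 weeks than after 24 h may stay open, since 10 genes of fatty acid oxidation were lower at 2 weeks, but 0 array series hold both times, and the explanations cannot be told apart. Doses, which could differ between the compounds, were not given in the labels and stay untested.

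More features differed between clofibrate and gemfibrozil at 24 h (193) than at 2 weeks (13). Array series cannot be told apart from other explanations: with the series as a term the counts were 181 and 177, a ratio of 1.02, and within the series that holds every animal 8 and 114. The fit with the series as a term also took arrays instead of animals as samples, so its ratio does not show the series alone. Arrays 82 to 100, with 2 clofibrate and 3 gemfibrozil animals, gave 214 at 24 h, 87 of them among the 193. The 24 h count itself thus differed between series, 8 against 214. The 2 features within arrays 102 to 135 at 2 weeks rest on 1 clofibrate animal. Without centring the counts were 23 and 15, a ratio of 1.53, so that centring cannot be told apart from a change of both counts with the scale. A biological difference between the times stays open and untested.

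D-mannitol animal 62 was the highest of the 4 D-mannitol animals in 5 of 11 markers of exocrine pancreas, genes that were chosen after their values were seen: Pnlip (3.15), Clps (2.91), Pla2g1b (1.76), Ctrb1 (1.48) and Cpb1 (1.07). Pancreas tissue in the sample is a possible explanation, but it could not be told apart from chance among animals, since Cpa1 (0.96), Cela1 (0.31) and Reg1a (0.33) were not highest there. Array series cannot be told apart either: over all 11 markers the animal exceeded the others by 1.70 ± 0.37 (SE over markers) in arrays 102 to 135 and by 0.84 ± 0.57 in arrays 137 to 179, where it has 1 array. Wyeth 14,643 animals 51 and 53 were high in Pnliprp1 (3.78 and 4.71) and Reg3b (2.87 and 4.14) at 2 weeks. Animal 51 was also above D-mannitol animal 62 in Gp2 (6.69), Cpa1 (3.44), Pla2g1b (2.40), Ctrb1 (1.72) and Cpb1 (1.36). It was below that animal in Pnlip, Clps, Cela1 and Reg1a. Of the Wyeth 14,643 group's values of Pnliprp1 and Reg3b, 44.4% and 33.3% stood at the floor or beyond 4 on the centred log2 scale. Without floor and tail values the group's means against the reference fell from 2.78 to 0.66 (adjusted p = 0.224) and from 2.14 to 0.64 (0.0947). In D-mannitol animals, those of Clps and Pnlip went from 1.14 to 0.54 and from 0.82 to 0.60. No biological explanation was tested.

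Other splits of the animals into groups of the same size bear on whether chance can be excluded. For the peroxisome proliferators against phenobarbital at 24 h, 133 features were called and at most 8 in any other of 100 splits (1 as large, the real one). The other splits could mix compounds within groups, which widens the pooled spread and lowers their counts in advance. With all 3 gemfibrozil animals set apart as if they were phenobarbital, 1 feature was called. The low counts go with animals of a compound being alike and do not by themselves exclude chance for this comparison. At 2 weeks 5 of 100 splits gave at least 131, up to 465, so this count does not exclude chance. The 4 others (465, 370, 229 and 154) set 2 or 3 Wyeth 14,643 animals apart as if they were phenobarbital, which points to a structure of the samples: they carry the difference of that compound and are no measure of chance. Other values argue against chance for the enzymes, with Ephx1 at -2.83 ± 0.23 (adjusted p = 2.7e-08) and the CAR and PXR targets past with an estimated correlation (4.6e-05). Against D-mannitol 1 of 35 splits, the real one, was as large for Wyeth 14,643 (447, highest other 347), phenobarbital (34, highest other 7) and gemfibrozil (8, highest other 4). That share is under 0.05 for each, without adjustment over the comparisons. These other splits also mix compounds within groups, which widens the pooled spread and lowers their counts in advance. They do not by themselves exclude chance for these 3 compounds. Nor can chance be excluded for clofibrate (2, highest other 14), where 3 of 35 were as large.

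The comparisons of 3 with 3 animals allow only 10 splits, which are too few for a share under 0.05. At 24 h clofibrate and gemfibrozil gave 193 features with 0 in the highest other split, clofibrate and Wyeth 14,643 42 with 3, and gemfibrozil and Wyeth 14,643 172 with 0. At 2 weeks the values were 13 with 5, 430 with 40 and 279 with 35. Between times they were 240 with 3 for clofibrate, 8 with 0 for gemfibrozil, 674 with 67 for Wyeth 14,643 and 0 with 0 for phenobarbital (172 unadjusted in limma for the real split).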
